A study of Mus musculus with 4 samples.

How the data were processed

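CUT&RUN, in which an antibody directs a nuclease to cut and release chromatin around a bound protein, was carried out with an anti-MYCN antibody on mouse liver tumors driven by MYCN and AKT and on matched non-tumor liver, per the labels. Sonicated input chromatin of each tissue was the negative control. The 4 libraries form 4 groups of 1 library each: tumor anti-MYCN, tumor input, non-tumor anti-MYCN and non-tumor input. The DNA was extracted with phenol and chloroform before library preparation, per the labels' protocols. The submitters' processing notes name Bowtie2, deepTools, MACS2 and HOMER and the builds GRCm38 and mm10, without versions or order. Per the file's peak names, each anti-MYCN library was called against input; the settings are not given in the sources used here.

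The deposited table lists peaks by name, with chromosome, start, end, length, a paired gene, the side of that gene on which the peak lies, and a q-value column. The q-value column holds −log10 q as the authors' peak caller gave it, judged from its lowest tumor value of 1.30, just above −log10 of 0.05. It was used here to describe, rank or filter peaks within each list. Each tissue has 1 list, so replicates cannot be compared. The table has no read counts, signal or fold enrichment, so the depth of the libraries is unknown. Rows with the same interval, which differ in their paired gene, were merged: 1620 tumor rows became 1617 peaks and 61 non-tumor rows became 55.

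Gene positions came from a RefSeq gene table of the same build, in which 99.3% of the gene names paired with tumor peaks and 97.7% of those paired with non-tumor peaks were found. That table was used without strand, and no genome sequence was used. The design fixed before the data were examined called a promoter peak a peak with its centre within 1 kb of a transcription start site. Here it is instead a peak with its centre within 1 kb of either end of a gene. E-box content, a background matched on base composition and a ratio of tumor to non-tumor signal were not analysed here. The score of promoter peaks per gene list was not computed, because no list had enough of them.

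Peak numbers near gene ends were set against 1000 random placements of each peak on its own assembled chromosome, between its outermost annotated genes. The p for an excess was one-sided, as fixed beforehand; the one-sided p for a deficit, and the count of peaks lying over a gene end, were added after the data were seen. Intervals of these ratios are exact Poisson limits of the observed count over the random mean, and intervals of shares are exact Clopper-Pearson intervals at 95%. All cover counting error only and treat peaks as independent. The overlap of the lists was taken at 1 bp or more with bedtools 2.31.1. The 27 gene lists, with 863 genes, were tested with one-sided Fisher exact tests against 21787 protein-coding genes, with Benjamini-Hochberg adjustment over the lists. Chromosome densities were tested with two-sided exact binomial tests, each autosome against the other autosomes and X and Y against all autosomes; this was added after the data were seen. A cluster is 3 or more peaks of a tissue with neighbours at most 10 kb apart. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

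The placement and list tests were tested on simulated data with the 1527 tumor peaks of assembled chromosomes and 21774 genes. With no peaks planted at gene ends, 0 of 20 simulations were called. With 50 planted, 20 of 20 were called, at a mean ratio of 2.00, and a list given 5 planted genes was called in 20 of 20. Without planting the simulated mean ratio was 0.970, above the 0.584 of the observed tumor peaks. Planting on such a lower baseline was not simulated, so recovery in these data may be poorer. Smaller plantings and deficits were not simulated, so the power for them is unknown.

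The genes named are those of the 10 strongest promoter peaks, 11 genes in tumor because Dnajc3 and Uggt2 share a peak, up to 4 members of each list with promoter peaks, and 13 genes fixed beforehand (Mycn, Myc, Max, Mnt, Mxi1, Odc1, Ncl, Npm1, Cad, Cdk4, Ldha, Alb and Afp). Genes named outside this rule were chosen after their values were seen. Some items are not reported here. Alternatives were the peaks at or above their list's median −log10 q, distances of 500 bp and 3 kb, the gene paired by the authors at any distance, all annotated genes as background and a reciprocal overlap of 50%. With 1 library per group, no p-value between tumor and non-tumor liver can be given.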

Results

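Anti-MYCN CUT&RUN peaks were available for 1 tumor library and 1 non-tumor liver library, each with a sonicated input as control. There were no replicates, so differences between the tissues have no replicate check. The study asks which genes MYCN, a MYC-family transcription factor, occupies in liver tumors driven together with AKT. Coordinates are in GRCm38.

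The tumor library had 1617 peaks covering 442078 bp and the non-tumor library 55 peaks covering 39586 bp, a ratio of 29.4 in number. The strongest peak of both lists lay on chromosome 2 near 98.7 Mb, in a region the authors paired with Lrrc4c, a synaptic adhesion gene whose nearer end is over 1 Mb away. Tumor peaks had a median length of 188 bp and a median −log10 q, the authors' own score, of 6.35. Non-tumor peaks had a median length of 283 bp. A −log10 q of 10 or more was reached by 501 tumor peaks (31.0%) and 26 non-tumor peaks. Of the tumor peaks, 871 (53.9%) had a −log10 q shared by at least 10 peaks, and a single value, 4.33, was shared by 126.

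Many of the strongest tumor peaks lay in a few regions. Whether the authors left out regions prone to artefactual peaks is not given in the sources used here, and none were left out here. On chromosome 9, 3000004 to 3038307 held 23 peaks, with a −log10 q of up to 6863. On chromosome 2, 98662245 to 98667306 held 4 peaks, the highest at 25412, and on chromosome 14, 19415721 to 19419450 held 6, the highest at 8609. In all, 12 clusters held 131 tumor peaks (8.10%), 6 of the clusters on assembled chromosomes. Of the 50 strongest tumor peaks, 47 lay in a cluster or on a scaffold. Outside clusters and scaffolds, the strongest tumor peaks lay at chromosome 9, 35305232 to 35305579 (−log10 q 6712) and chromosome 12, 3109889 to 3110113 (3202). The first was shared with non-tumor liver, and their paired genes lay 19809 and 125678 bp away. Weaker ones included one inside Chl1, a neural adhesion gene (chromosome 6, 103649082 to 103649262, −log10 q 1236). Another lay inside Mocos, the molybdenum cofactor sulfurase gene (chromosome 18, 24677123 to 24677528, 637). These peaks were chosen after their values were seen.

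Genes with a tumor promoter peak were few. Such a peak can lie at either end of a gene, so it need not be at the start. Adgb, which encodes androglobin, had the strongest (chromosome 10, 10335293 to 10335609, −log10 q 332.8), on the downstream side. A peak at chromosome 14, 118982407 to 118982706 (118.3) lay 705 bp downstream of Dnajc3, an endoplasmic reticulum co-chaperone gene, and inside Uggt2, a glycoprotein glucosyltransferase gene. Stc2, which encodes the secreted glycoprotein stanniocalcin, had a peak 234 bp upstream (chromosome 11, 31370295 to 31370490, 116.2). Ms4a4a (18.8), the ribonucleoprotein assembly gene Shq1 (12.2), Them7 (11.7), the translation gene Paip1 (11.6), the olfactory receptor gene Olfr16 (10.9), the RNA polymerase subunit gene Polr3gl (10.6) and the receptor gene Relt (8.40) completed the 10 strongest promoter peaks. Paip1, Polr3gl and Relt had their peaks upstream, at gaps of 35, 356 and 152 bp. By the authors' pairing the Olfr16 peak was downstream, and the peaks near Ms4a4a, Shq1 and Them7 belonged to other genes. Weaker peaks lay downstream of the hepatokine gene Fgf21 (5.54) and upstream of Gdf2, a liver-expressed growth factor gene (1.30). Both were chosen after their values were seen. Altogether 29 protein-coding genes had such a peak.

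Tumor peaks were not enriched at gene ends. Of 1527 peaks on assembled chromosomes, 28 (1.83%) lay within 1 kb of an end of a protein-coding gene, against a mean of 47.97 in random placements (ratio 0.584, 95% interval 0.388 to 0.844, one-sided p for an excess 0.998). The one-sided p for a deficit was 0.003996, but among peaks with a −log10 q of 10 or more it was 0.147 (ratio 0.686, 0.314 to 1.30). No tumor peak lay over an end of a protein-coding gene, against a random mean of 6.49 (upper limit of the ratio 0.569, one-sided p for a deficit 0.001998). Over all annotated genes 1 peak, at the long noncoding RNA gene Lnclep (chromosome 6, 29030714 to 29030956), lay over an end, against a random mean of 13.9 (ratio 0.0719, 0.00182 to 0.4004, one-sided p 0.000999, the smallest that 1000 placements can give). By the authors' pairing, 746 tumor peaks (46.1%) were upstream of their gene, 418 (25.9%) downstream and 385 (23.8%) inside; 0 overlapped the start of their gene and 1 its end, while 1 non-tumor peak, at Sp110, overlapped the start. Of upstream peaks whose gene was found, 28 of 718 (3.90%) lay at most 1 kb away, and of downstream peaks 19 of 416 (4.57%), with a two-sided Fisher exact p of 0.643. The median gaps were 33240 and 48978 bp. Inside protein-coding genes lay 583 peaks (38.2%), a ratio to random placement of 0.933 (0.859 to 1.01, one-sided p for a deficit 0.014). Here the Poisson interval and the p differ because the p comes from the placements, whose central 95% ran from 588 to 662 peaks. At a −log10 q of 10 or more the ratio was 0.807 (0.679 to 0.953, p 0.000999). Without clusters, scaffolds and shared positions it was 0.963 (p 0.133), and with both filters 0.902 (p 0.0519). Of non-tumor peaks, 12 of 53 lay inside such genes (ratio 0.543, p 0.001998), and 12 of 36 without clusters, scaffolds and shared positions (0.791, p 0.1998).

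**Figure D1:**
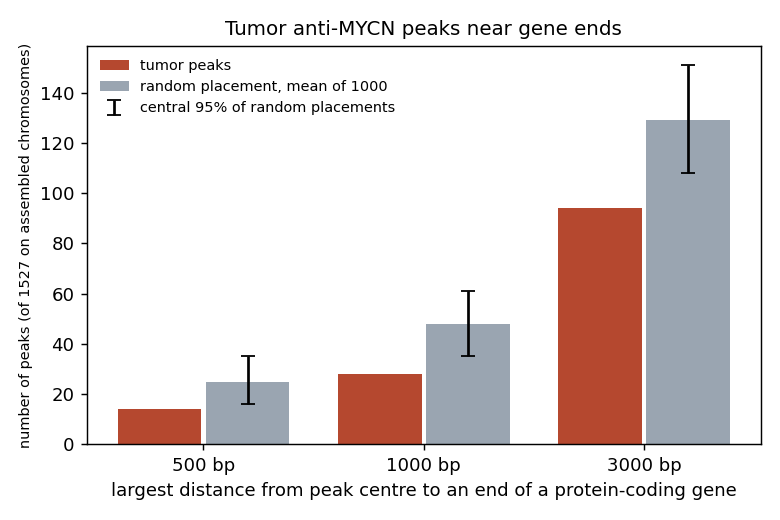
Number of tumor anti-MYCN peaks (y axis) whose centre lies within 500, 1000 or 3000 bp of an end of a protein-coding gene (x axis), beside the mean of 1000 random placements, with error bars that mark the central 95% of placements. The tumor counts of 14, 28 and 94 lie below the random means of 24.96, 47.97 and 129.1 and below the central range at each distance.

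Genes often used as MYC targets carried no tumor promoter peak. Only 29 of 21787 protein-coding genes had one, so this absence says little about these genes. The gaps below were not set against random placement. The gap from the gene to the closest tumor peak was 42862 bp for the cell cycle kinase gene Cdk4, 70522 bp for the MAX partner gene Mnt and 137553 bp for Mycn. It was 268680 bp for Max, 347643 bp for the nucleolar gene Npm1, 894169 bp for the pyrimidine synthesis gene Cad and 907702 bp for the polyamine synthesis gene Odc1. For Myc, the nucleolin gene Ncl and the lactate dehydrogenase gene Ldha it exceeded 1 Mb (1134951, 1233707 and 1229093 bp). The albumin gene Alb and the fetal gene Afp had gaps of 358739 and 388583 bp. Mxi1, which encodes a MAX-binding repressor, held a weak peak inside the gene (chromosome 19, 53348821 to 53348987, −log10 q 1.46).

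None of the 27 gene lists was enriched for tumor promoter peaks by the one-sided Fisher exact test, with 0 lists at an unadjusted p under 0.05. A list needed 2 or 3 genes with a peak to pass, and the list of olfactory receptors, a control of silent genes, was alone in having any, with Olfr16. Counting instead a peak in the gene or within 10 kb of it, against random placement, ribosome biogenesis had 0 of 60 genes (random mean 1.554), cytosolic ribosomal proteins 0 of 79 (1.07), mitochondrial translation and import 0 of 60 (1.35) and hepatocyte secreted and metabolic genes 0 of 60 (1.504). The lists of purine and pyrimidine synthesis, one-carbon and serine metabolism, polyamine synthesis, glycolysis, splicing, lysosome and autophagy, cholangiocyte, endothelial and macrophage markers and the AKT pathway also had 0. The MYC and MAX network had 3 of 23, Hdac2, Kat5 and Mxi1 (random mean 0.797, one-sided p 0.04396, adjusted p 1). There were 2 genes each for aminoacyl-tRNA synthetases (Aars, Lars), chaperones (Hspd1, Hspe1), lipid synthesis (Elovl6, Gpam), cell cycle inhibitors and the p53 pathway (Gadd45a, Mdm2), circadian genes (Arntl, Rora), hepatocyte transcription factors (Prox1, Ppargc1a) and liver progenitor markers (Cd44, Lin28b). Cell cycle and replication (Cdk6), translation factors (Eif3l), stellate cell (Reln), lymphocyte (Lck) and olfactory receptor (Olfr16) lists had 1 each. No list passed after adjustment.

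By the authors' pairing at any distance, 29 genes of the lists had a tumor peak. Liver progenitor markers had 4 of 25, Cd24a, Cd44, Glul and Hmga2 (one-sided Fisher exact p 0.0285, adjusted p 0.685), and one-carbon metabolism had 3 of 18, Mat2a, Psat1 and Slc1a4 (p 0.0507, adjusted p 0.685). The median gap of these peaks was 24688 bp, and 20 of 32 were over 10 kb away.

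In non-tumor liver, 3 genes had a peak centred within 1 kb of either gene end. Strand was not used, so none of them is shown to lie at the start of its gene. Mycn itself held a peak of −log10 q 12.5 (chromosome 12, 12936710 to 12937307), inside the gene and centred 915 bp from its nearer end. Afp, the fetal liver gene, held one of 4.47 (chromosome 5, 90507772 to 90508632), and Lars2, a mitochondrial tRNA synthetase gene, one of 28.5 (chromosome 9, 123461841 to 123462161). The authors paired these peaks with other genes, as upstream of Afm and of Limd1. Against random placement the 3 of 53 peaks gave a ratio of 1.78 (0.366 to 5.19, one-sided p 0.234). With all annotated genes 9 of 53 lay there (ratio 2.66, 1.22 to 5.06, one-sided p 0.001998), and at 500 bp from protein-coding genes 0 did. The count with all annotated genes at 1 kb was not repeated without clusters and shared positions. Its peaks included one over pseudogenes, one in a cluster of 3 and one at a shared position near Mir101c. The MYC and MAX network and the liver progenitor list passed the one-sided Fisher exact test (adjusted p 0.0464 each), each on a single gene, Mycn and Afp, and both calls were lost at 500 bp and at 3 kb. Other non-tumor peaks included 9 between 14982220 and 15703706 on chromosome 5, around Speer4 genes, and one of 4627 bp over the pseudogenes Gm10222 and Gm10925 on chromosome 1 (24611544 to 24616170, −log10 q 1756). These regions were chosen after their values were seen.

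Of the 55 non-tumor peaks, 14 (25.5%, 14.7 to 39.0) overlapped a tumor peak, against a mean of 0.015 when tumor peaks were placed at random. The shared positions included Gt(ROSA)26Sor (chromosome 6, 113076025 to 113076235), the regions near Lrrc4c on chromosome 2 and Gm2237 on chromosome 14, 4 positions in the chromosome 9 cluster at 3000004 to 3038307, and chromosome 9, 35305268 to 35305551. The 14 tumor peaks there had a median percentile of 99.1 by −log10 q among tumor peaks. With neighbours within 10 kb counted once, the 9 shared regions had a median percentile of 98.8 (two-sided permutation p 1e-05, the smallest that 100000 resamples can give), while 2 of the 9, near Ofcc1 and Cd180, lay below the median region. The Mycn, Afp and Lars2 peaks of non-tumor liver overlapped no tumor peak. Whether the tissues differ at these genes cannot be tested with 1 library each.

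Tumor peaks outside clusters were spread unevenly over chromosomes (permutation p for an even density over the 19 autosomes 0.00233). Chromosome 19 had 60 peaks against 34.9 at the density of the other autosomes (ratio 1.72, 1.30 to 2.23, adjusted p 0.000838), and chromosome 2 had 76 against 111.7 (ratio 0.681, 0.533 to 0.858, adjusted p 0.00365). The X chromosome had 14 against 102.3 (ratio 0.137, 0.0747 to 0.230) and Y had 4 against 55.2 (ratio 0.0724). At or above the median −log10 q, chromosome 19 had a ratio of 1.86 (adjusted p 0.0167), chromosome 2 0.738 (adjusted p 0.354) and X 0.148 (adjusted p 4.37e-11). Among the fewer peaks with a −log10 q of 10 or more the ratios were 1.89 (1.09 to 3.08, adjusted p 0.120), 0.694 (0.419 to 1.09, adjusted p 0.614) and 0.114 (0.0233 to 0.335, adjusted p 7.91e-07).

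**Figure D2:**
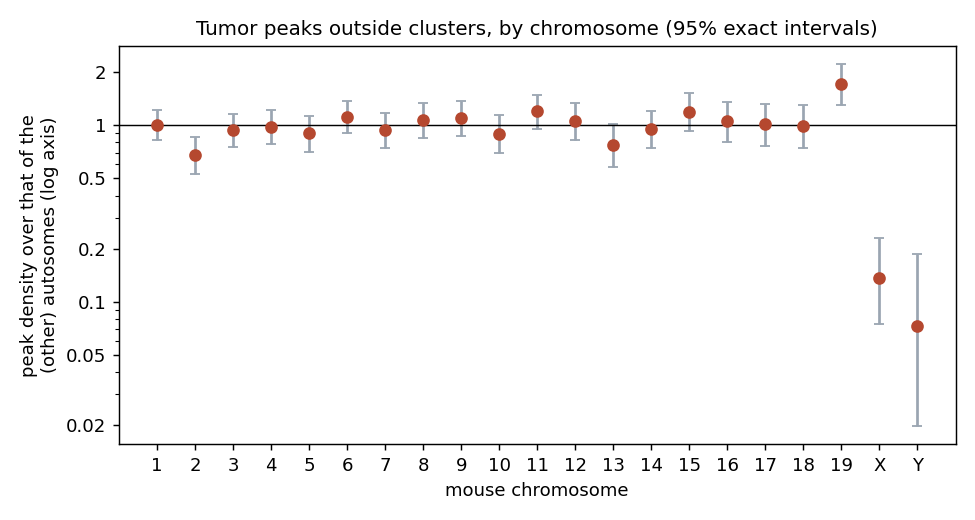
Density of tumor peaks outside clusters on each chromosome (x axis) over that of the other autosomes, or of all autosomes for X and Y (y axis, log scale), with exact 95% intervals. Chromosome 19 lies above 1 at 1.72, and chromosomes 2, X and Y lie below at 0.681, 0.137 and 0.0724.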

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

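The tests in this part were chosen after the results were seen. Signal appeared outside the assembled nuclear chromosomes that the gene comparisons use. Tumor liver had 90 peaks on unplaced or unlocalized scaffolds and non-tumor liver 1. Non-tumor liver also had a peak over nearly the whole mitochondrial chromosome, positions 2 to 16297, with a −log10 q of 3105.25.

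The strongest tumor peaks lay in clusters, on scaffolds and at positions shared with non-tumor liver. Reads from repeated sequence, piled on collapsed copies in the assembly in both tissues, are a possible account of the shared positions. With neighbours within 10 kb counted once, the 9 shared regions had a median tumor percentile of 98.8 (two-sided permutation p 1e-05, the smallest possible). Strong signal of either origin is more readily called in both lists, so this value cannot tell repeats from MYCN binding. The shared peaks near Ofcc1 and Cd180 were weak, with tumor −log10 q of 4.40 and 2.96, below the tumor median of 6.35. Repeats were not identified here, since no sequence was used, and MYCN binding in both tissues stays open. Whether the same repeats lie behind the scaffold peaks stays open: 0% of the 90 tumor scaffold peaks (upper limit 4.02%) overlapped a non-tumor peak, but the non-tumor list is short and its depth unknown.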

How the results depend on the processing

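The settings with a −log10 q of 10 or more, without clusters, scaffolds and shared positions, with both together, with all annotated genes near gene ends, and with gene bodies against random placement were chosen after seeing the data. At or above the median −log10 q, peaks numbered 813 in tumor and 28 in non-tumor liver, and at 10 or more 501 and 26, fewer by construction. The tumor ratio at gene ends stayed below 1 under all 7 alternatives, from 0.531 to 0.788; its deficit was not called at a −log10 q of 10 or more, with all such peaks (0.686, p for a deficit 0.147) or without clusters, scaffolds and shared positions (0.788, p 0.325), where peaks are fewer. Of the tumor gene lists, 0 passed under any of another 7 alternatives. These included the paired gene at any distance and gene bodies, and the lists were not run at a −log10 q of 10 or more. The non-tumor ratio turned to 0 at 500 bp, where no peak remained. It rose to 2.66 past the threshold (one-sided p against random placement 0.001998) with all annotated genes. That setting was not run without clusters, scaffolds and shared positions, and it counts peaks as independent. Near protein-coding genes the ratio was 2.62 at a −log10 q of 10 or more (one-sided p against random placement 0.184). Without clusters, scaffolds and shared positions it was 2.64 (p 0.104). With both filters it was 4.07 (p 0.0869), on 2 peaks. The cause was not tested. The 2 non-tumor lists fell to 0 at 500 bp, at 3 kb, by paired gene, at or above the median −log10 q, with all annotated genes and with gene bodies; each rested on 1 gene. The overlap stayed between 18.2% and 30.8%. Not run were the alternatives for E-boxes, promoter base composition, tumor to non-tumor signal and the score of gene lists; the paired gene at any distance gives no ratio at gene ends. No paired analysis was possible because each group has 1 library. Depth is unknown, which limits every count of peaks.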

Other observations

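Of the tests in this part, the one on repeated −log10 q values was fixed before its result was seen; all others, and the gene families, were chosen after. Tumor peaks lay in or within 10 kb of several long neuronal genes, among them the adhesion genes Cntnap2, Cntn4, Nlgn1, Tenm2, Tenm3, Tenm4 and Cdh13 and the glutamate receptor genes Grm7 and Grin3a. Over 5 neuronal families (cadherins, contactins, potassium channels, glutamate receptors, and teneurins with their synaptic partners), 23 of 183 genes had such a peak, against a random mean of 25.3 (central range 18 to 33, one-sided p for an excess 0.768). Among the 227 protein-coding genes longer than 500 kb, 77 had one against 88.6 (one-sided p 0.955).

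Tumor peaks had no excess at gene ends, and 0 lay over an end of a protein-coding gene. Dilution of promoter peaks by randomly placed calls predicts a ratio of 1 or more, since such calls pull it toward 1 from above. The ratio of 0.584 over all peaks, with an upper limit of 0.844, argues against it only if no peaks over gene ends were removed. Beside a protein-coding end but not over it the upper limit was 0.963, but beside any annotated end it was 1.01. Weak or repeat-like calls that themselves avoid gene ends could still hide a small excess: peaks with a −log10 q of 10 or more outside clusters, scaffolds and shared positions had a ratio of 0.788 (0.360 to 1.495), and the bound for excluding an excess was moved from 2 to 1 after this value was seen, without which it would have been excluded. For calls with repeated scores the same stays open, although 1.49% of them and 2.29% of the other peaks (15 of 656, upper limit 3.74%) lay within 1 kb of an end, both below the random 3.14% (odds ratio 1.54, 0.680 to 3.55, two-sided Fisher exact p 0.256). Removal of tumor peaks over gene ends could explain the absence there, with a ratio of 0.805 (0.634 to 1.01) beside an annotated end and 0.682 (0.466 to 0.963) beside a protein-coding end, and the non-tumor peaks of the same table do not settle it: 2 of 53 lay over an annotated end, at pseudogenes and a snoRNA gene, 0 over a protein-coding end (random mean 0.372), and the one the authors put over the start of Sp110 lies inside that gene in the RefSeq table.

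Few tumor peaks lay on the X chromosome. A single X copy, with calls in proportion to copies, is argued against by the density ratio of 0.137, whose upper limit of 0.230 lies below 0.5. Low gene density is argued against by a ratio of 0.135 (0.0725 to 0.230) to chromosomes 1, 12 and 18, the 3 autosomes closest to X in genes per Mb, which had ratios of 1.01, 1.05 and 0.993. A caller threshold that few X regions pass could still act on a lower copy number, and the sex of the animals is not given in the labels used here. No biological explanation was tested.

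Over the 19 autosomes, peaks per Mb and genes per Mb had a Pearson r of 0.313 (permutation p 0.193, adjusted p 0.385) and a Spearman rho of 0.154 (permutation p 0.526, adjusted p 0.578). Without the 2 chromosomes farthest from the median gene density, r was 0.410 (permutation p 0.107, adjusted p 0.385) and rho 0.145 (permutation p 0.578).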
